A study of Drosophila melanogaster with 2 samples.

How the data were processed

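Chromatin immunoprecipitation with an antibody against GFP, per the description of the samples, and sequencing was carried out on embryos of 1 transgenic line, in 2 biological replicates numbered 2 and 3 in the labels, with chromatin broken by sonication to a size range of 200 to 800, per the labels. There was 1 group and no contrast between groups. Control reads were not analysed here, and the sources used here name a control alignment without saying what it holds.

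The deposited files are peak lists in narrowPeak format on the dm3 and dm6 builds. For each build there is a relaxed list per replicate, a relaxed list from both replicates together, and a list thresholded for reproducibility between replicates from those 3, per the text that accompanies the deposited files. The peak caller, the aligner, their versions, the filters and the reproducibility cut are not given in the sources used here. Each peak has the authors' signal value, which is used here only to describe and rank peaks within a list, since its scaling between libraries is not given. Each peak also has a deposited −log10 q value, which reached a ceiling of 3.94 at 4383 pooled peaks on dm6, all thresholded peaks among them, and so could not rank them. Each relaxed list holds 30000 peaks, with a median width of 400 bp in the pooled list. The 2876 thresholded peaks on dm6 were the 2876 strongest of the pooled list, with the same signal, between 61.8 and 1231. Read depth is unknown, since the lists hold no read counts, and no floor on counts was set. Intervals on shares are 95% Wilson intervals over peaks, which cover counting error only and treat neighbouring peaks as independent.

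Sequence came from the NCBI Release 6 assembly and gene models from Ensembl release 115 on BDGP6.54, whose arms have the lengths of dm6. Sequence and gene results therefore use the dm6 lists, and no coordinate was converted between builds. Annotation was limited to 13968 protein-coding genes with 19630 transcript starts on arms 2L, 2R, 3L, 3R, 4, X and Y. Positions are counted from 1. Annotation classes were taken in the order promoter (within 500 bp of a start), 5′ UTR, 3′ UTR, coding exon, intron and intergenic; exon parts of coding genes outside UTRs were counted with coding exons.

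Replicates were compared by their strongest 2876 peaks, with summits within 200 bp counted as shared, against 1000 circular shifts of 1 list along each arm. Positions and spacing of summits were compared with 1000 random placements on the same arm off assembly gaps. Words were searched on both strands within 100 bp of the summit and in 2 flanks centred 1000 bp to each side; shares of flanks are over both, and the exact McNemar test used 1 flank per peak chosen by a seeded coin. All 7-mers were compared with the flanks by Fisher's exact test with Benjamini-Hochberg adjustment. Gene lists were compared with 100000 random lists matched on the number of starts (1, 2, 3 or more) and gene length quintile. All permutation p-values are two-sided. Values of arms were tested by exact binomial tests. The replicates are separate biological samples by the labels, but no test over the 2 samples was run, and all p-values are over peaks or genes.

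The lists, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise. Fisher's exact test of promoter against distal peaks, the annotation classes other than promoter, the split of the other words by place and the bins along the relaxed list were added during the analysis. Also not fixed beforehand were the alternatives that took relaxed pooled peaks below the threshold as background for the promoter share and for the search over all words of fixed length. The text names the genes nearest the 20 strongest thresholded peaks, from each list the 4 bound genes with the highest signal and up to 3 genes not bound in list order, the 5 peaks in each direction with the largest difference of rank between replicates, the 5 genes with the most summits, and zld. Of the 19 lists, 2 names in the Enhancer of split and Bearded list were not matched; older symbols were matched through the NCBI gene table, so that h appears as hry and Neu3 as Meltrin. Alternatives were the strongest 1438 thresholded peaks, each replicate's strongest peaks alone, the dm3 build, other windows, flanks, words, distances and assignments of summits to genes.

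The statistics were tested on simulated data. With nothing planted, 0 of 8192 pairs of 7-mers passed at random places in the genome, and a word planted in 5% of 2876 windows put both of its 7-mers first. In the McNemar test of CAGGTAG, 4 of 200 random sets had p under 0.05, and a site planted in 1% of 2876 windows was found in 82 of 100 sets. In the gene list test, 2 of 200 random lists of 20 genes had p under 0.05, and lists with 60% of genes bound were found in 95 of 100. A pair of lists built to share 49.9% of summits were measured at 51.0%. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.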

Results

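Binding of Zelda was mapped in whole Drosophila melanogaster embryos by chromatin immunoprecipitation followed by sequencing. Zelda, the product of zld (also called vielfaltig, vfl), is a zinc finger pioneer factor that opens early embryonic enhancers and starts zygotic transcription, and its textbook site is the 7-base word CAGGTAG. The flies carried zld fused to GFP, and by the description of the samples the tagged protein was precipitated with an antibody against GFP, although the antibody field of the labels reads vfl. The embryos were of mixed sex and aged 0 to 24 hours. The series held 1 group with 2 biological replicates, numbered 2 and 3 in the labels, so the questions were where the tagged protein was found, which sequence and genes lay there, and how well the replicates matched. Each replicate had a relaxed list of 30000 peaks, the pooled reads had another of 30000, and the authors' reproducibility threshold kept 2876 peaks on the dm6 build. Read depth is unknown, because the files give peaks and not read counts. In what follows a gene is called bound when a thresholded summit lay within 1 kb of one of its annotated starts.

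The thresholded peaks lay mainly at promoters. Of the 2876 summits, 1856 (64.5%, 95% Wilson interval 62.8 to 66.3%) fell within 500 bp of the start of a protein-coding transcript, against 11.5% of randomly placed summits. The share was 64.3% ± 1.20 (SD, n = 2) when each replicate's own 2876 strongest peaks were used, so the difference from random placement was far larger than the spread between replicates. It was 5.61 times the random share (permutation p = 0.002, two-sided, the smallest that 1000 placements can give). Introns away from starts held 23.8% of summits against 39.3% at random, and intergenic sequence held 10.4% against 29.97%. Coding exons held 5 summits (0.174%, interval 0.0743 to 0.406%) against 13.3% at random, and 3′ UTRs held 0.626% against 5.14%. The relaxed pooled peaks below the threshold were spread more widely, with 27.3% near a start and 11.7% in coding exons.

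**Figure D1:**
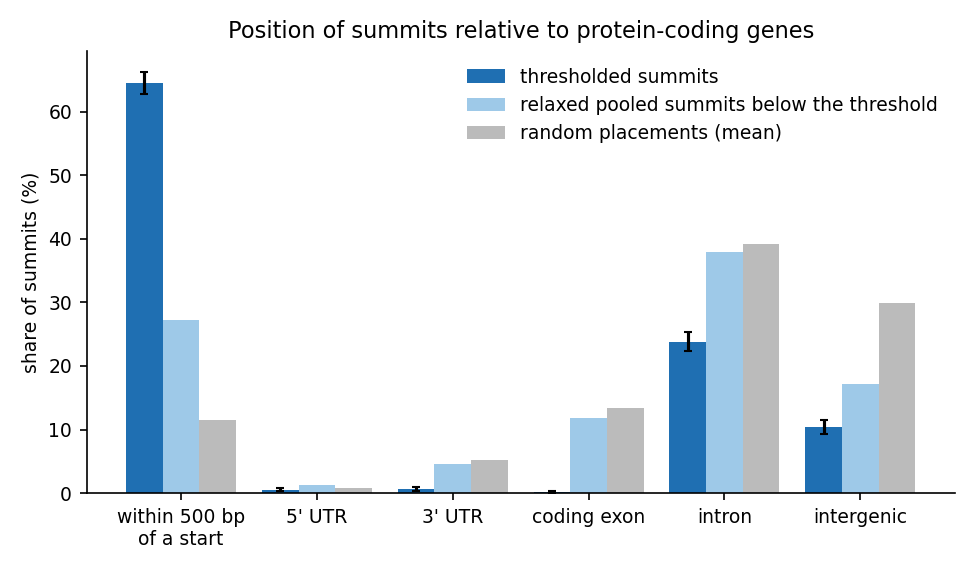
Share of summits (%) in each annotation class for the 2876 thresholded peaks (dark bars, with 95% Wilson intervals), the relaxed pooled peaks below the threshold (light bars) and the mean of 1000 random placements (grey bars). Thresholded summits lie within 500 bp of a start in 64.5% of cases, against 11.5% at random, and in coding exons in 0.174%.

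The 20 strongest peaks were strong in both replicates, and most lay close to a start. The highest deposited signal, 1231, belonged to a summit on arm 3L at position 19590620, 96 bp upstream of the start of CG14100, and this peak ranked 1 in both replicates. Next came a peak with signal 1075 at 2L position 481086, 1398 bp upstream of the nearest start, that of cbt, which encodes a zinc finger transcription factor. A peak with signal 944 at 2L position 6612721 lay inside CG11050, 1034 bp downstream of its start. Ugalt, a nucleotide sugar transporter gene, had signal 890, and Chro, which encodes the chromosomal protein Chromator of polytene interbands, had signal 810. PNPase, the polynucleotide phosphorylase gene, had signal 724, and the wing vein gene px had signal 704. The genes nearest the other peaks among the 20 strongest were CG8320, CHMP2B, CG4004, HmgZ, Lk6, mRpL41, CG1888, larp, CG32772, CenG1A, the Polycomb group gene ph-p, CG9663 and GstE13. Each of these 20 peaks ranked at 33 or better in both replicates. None of the 20 held CAGGTAG within 100 bp of its summit.

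CAGGTAG was found near few thresholded summits. It lay within 100 bp of the summit in 58 of 2876 peaks (2.02%, interval 1.56 to 2.60%), against 1.44% in flanks centred 1000 bp away. The ratio of 1.40 did not pass the exact McNemar test (p = 0.184, two-sided). Promoter peaks and distal peaks differed in this respect. Of 1856 promoter peaks 25 (1.35%) held the word, and of 1020 peaks farther from a start 33 (3.24%) did (Fisher's exact test, p = 0.000799). At the distal peaks the share was 2.75 times that of their flanks (exact McNemar p = 0.000191). Among each replicate's own strongest peaks the distal share was 2.76% in replicate 2 and 5.08% in replicate 3. The promoter share was 1.21% and 1.49%. In replicate 3 taken alone, 2.75% of the 2876 strongest peaks held the word, 1.74 times the flanks (exact McNemar p = 0.00838), and in replicate 2 taken alone 1.77% did, 1.24 times the flanks (exact McNemar p = 0.182).

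CAGGTAG was less frequent at the stronger peaks. It was held by 10 of the strongest 1438 peaks (0.695%), with 2 of 288 at ranks 1 to 288 and 0 of 288 at ranks 289 to 576 and again at ranks 865 to 1152. At ranks 2590 to 2876 13 of 287 (4.53%) held it. Signal and presence of the word were negatively related across peaks, which are not independent replicates (Spearman rho = −0.0979, permutation p = 2e-05, the smallest that 100000 resamples can give). The sign was the same with the signal of replicate 2 (rho = −0.118, permutation p = 2e-05) and of replicate 3 (rho = −0.0472, permutation p = 0.0113). Along the relaxed pooled list the share rose from 0.5% at ranks 1 to 1000 to 3.6% at ranks 2001 to 3000, then declined to 2% at ranks 8001 to 9000. The replicates' own lists began at 1% (replicate 2) and 1.2% (replicate 3) at ranks 1 to 1000. Their highest shares were 3% at ranks 5001 to 6000 in replicate 2 and 3.9% at ranks 1001 to 2000 in replicate 3.

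**Figure D2:**
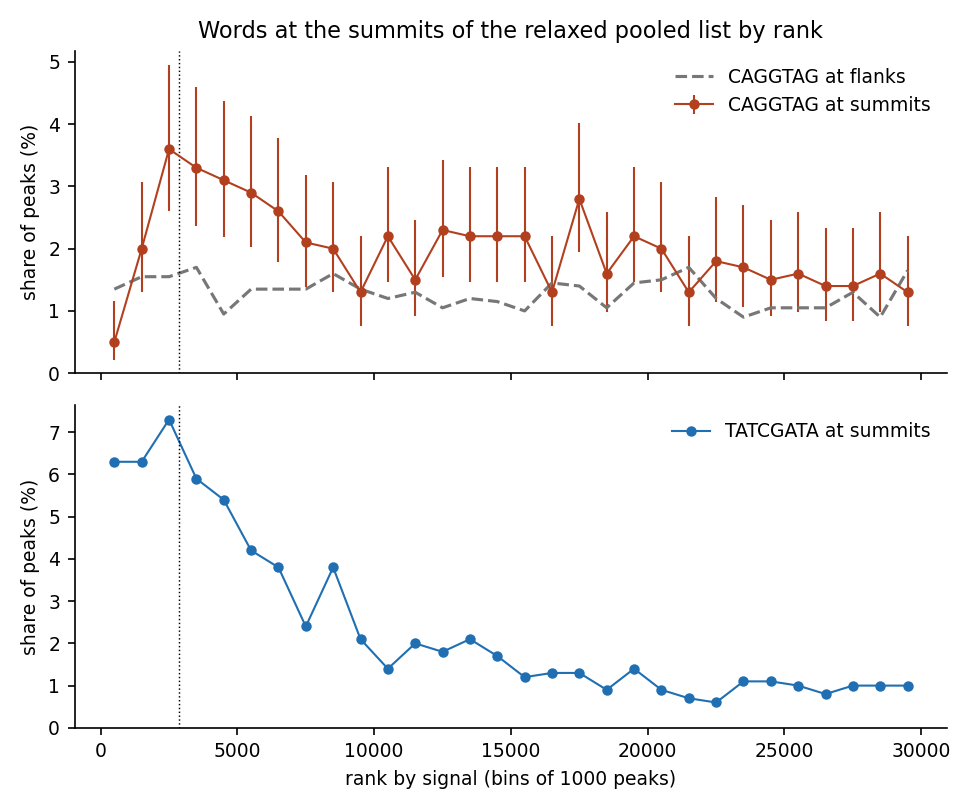
Share of peaks (%) with CAGGTAG (upper panel, points with 95% Wilson intervals; dashed line, flanks 1000 bp away) and with TATCGATA (lower panel) within 100 bp of the summit, in bins of 1000 peaks along the relaxed pooled list ranked by signal. The dotted line marks the authors' threshold at 2876 peaks; CAGGTAG is at 0.5% in the strongest bin and 3.6% at ranks 2001 to 3000, while TATCGATA is at 6.3% in the strongest bin.

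Other words were more frequent at the promoter peaks than in their flanks. The flanks need not be promoters, so these comparisons cannot tell the bound promoters from promoters in general. TATCGATA, the site of the promoter factor DREF, whose core is shared by the insulator protein BEAF-32, was present at 192 summits (6.68%) against 0.487% of flanks, a ratio of 13.7 (exact McNemar adjusted p = 1.72e-38 over 10 words). At promoter peaks it reached 10.1% against 0.404% of flanks, and at distal peaks it was found at 4 of 1020 summits (0.392%). GGTCACAC, the site of the core promoter factor M1BP, lay at 103 summits (3.58%), 5.15 times the flanks (exact McNemar adjusted p = 5.02e-13). Of the close relatives of CAGGTAG, TAGGTAG was at 1.63% of peaks against 0.974% of flanks (exact McNemar adjusted p = 0.0191), a ratio of 1.68. The call was lost in the strongest 1438 peaks (1.46% against 0.974% of flanks) and in replicate 2 (ratio 1.61) and replicate 3 (ratio 1.51) alone, though the word stayed more frequent than in flanks. CAGGTAA, CAGGCAG and CAGGTAT did not pass, nor did GAGAG, the GAGA factor type, or TAATCC, the Bicoid type. CACCTG, the Snail type, was less frequent at summits (6.33%) than in flanks (9.91%, exact McNemar adjusted p = 6.35e-08). The deficit lay at promoter peaks (6.03% against 11.6% of flanks), and distal peaks showed none (6.86% against 6.91%).

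The search over all 8192 pairs of 7-mers gave the same leading word. ATCGATA or its reverse complement lay at 380 summits (13.2%) against 2.35% of flanks, followed by the overlapping CTATCGA (9.63% against 1.65%) and ACTATCG (7.79% against 1.32%). Another group was led by AGTGTTG (9.91% against 2.36%), AACACTG (8.31% against 2.14%) and ACAGTGG (8.80% against 2.45%). In all, 1093 pairs were more frequent at summits and 1783 less frequent (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). Summit windows were poorer in G and C (37.9%) than the flanks (43.8%), and many of the pairs, such as TTTAAAA, hold A and T alone. In this search too the flanks need not be promoters.

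Genes of early patterning, whose enhancers are the known targets of Zelda, did not pass the test against matched random lists for summits within 1 kb of a start. Of 13968 protein-coding genes 2750 (19.7%) were bound. Among 20 genes of the first zygotic wave 5 were bound, where matched random lists gave 18.8%. They included Z600, an inhibitor of mitosis (signal 278, pooled rank 126), kuk (signal 185), btsz (signal 108) and the sex determination gene Sxl (signal 78.5). The X chromosome counting genes sisA and sc and the pair-rule gene run were not bound: their best relaxed summits stood at pooled ranks 15800, 6728 and 3814, and those of sisA and sc held CAGGTAG. Of 13 gap and head genes only hkb was bound (signal 64.0), while Kr fell short at rank 3256, hb stood at rank 19288 and kni had no pooled summit within 1 kb. Of 12 pair-rule genes only hairy (hry) was bound, at rank 2087 with CAGGTAG at the summit, and eve and ftz stood at ranks 16446 and 11236. Of 12 segment polarity genes only nkd was bound (signal 128), and en and wg were at ranks 10552 and 4691. Of 26 dorsoventral genes 7 were bound, among them brk (signal 116), tin (114.6), Meltrin (92.8) and ush (91.3), and zen had no pooled summit within 1 kb. None of the 8 homeotic genes was bound, with lab, pb and Dfd at ranks 12418, 17052 and 4454. With replicate 2 alone and replicate 3 alone, 0 and 2 gap and head genes, 1 and 2 pair-rule genes and 1 and 2 segment polarity genes were bound. Where each summit was given to the gene with the nearest start, segment polarity genes had 4 of 12 (ratio 1.40 in place of 0.350), dorsoventral genes 10 of 26 (1.73 in place of 1.13), homeotic genes 2 of 8, and gap and head and pair-rule genes 2 each, and none of these lists passed. Permutation tests against 100000 matched lists left all 6 of these lists inside the random range (adjusted p from 0.235 to 0.879 over 19 lists). For gap and head, pair-rule, segment polarity and homeotic genes that range began at 0 bound genes. These 4 lists were therefore too short to fall below it, and the test within 1 kb of a start cannot show less binding there. With summits counted in the gene extended by 2 kb, gap and head genes had 1 of 13 against a random range of 2 to 8 (ratio 0.217, permutation adjusted p = 0.115). The ratio there was 0.258 for pair-rule, 0.443 for segment polarity and 0.570 for homeotic genes. First-wave (1.26) and dorsoventral genes (1.21) lay above 1, and none of the 6 lists passed.

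Ribosomal protein genes and a control list of housekeeping and heat-shock genes were bound more often than matched random lists. Of 92 cytoplasmic ribosomal protein genes 53 (57.6%) were bound against 21.8% in random lists, a ratio of 2.64 (permutation adjusted p = 0.000127, from the smallest p that the draws can give). Each replicate's own list gave 51. The random lists here and below were not matched on neighbouring genes, and 1 summit between nearby starts can count for both genes. RpL34b (signal 373), RpS27 (345), RpL7 (321) and RpL32 (240) led them, and RpL10, RpL10Aa and RpL10Ab were not bound. The control list was written to hold highly transcribed genes, but it takes in heat-shock genes and transcription was not measured. Of its 19 genes 11 (57.9%) were bound against 27.5% (permutation adjusted p = 0.0318). Gapdh2 (signal 384), Hsp27 (307), Hsp83 (189) and Act5C (138) led them, while Act42A, Gapdh1 and Hsp70Aa were not bound. Of 48 proteasome genes 10 (20.8%) were bound against 17.0%, which did not pass (permutation adjusted p = 0.686). Replicate 2 alone gave 12 (ratio 1.53) and replicate 3 alone 7 (ratio 0.870), so the direction depended on the replicate. Rpn6 (signal 168), Rpn3 (152), Rpn5 (126) and Prosbeta1 (120) were the strongest of them.

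Of 13 pioneer or early chromatin factor genes 9 (69.2%) were bound against 29.4% in random lists (permutation adjusted p = 0.0262), with ph-p (signal 574), lola (199), the GAGA factor gene Trl (163) and grh (109) the strongest and Clamp, dl and odd not bound. The call was lost in the strongest 1438 peaks (ratio 2.70, permutation adjusted p = 0.0974) and when summits in the gene extended by 2 kb were counted (ratio 1.83, permutation adjusted p = 0.0749), against a ratio of 2.36 in the thresholded list with summits within 1 kb. zld itself was bound, with signal 70.3 at pooled rank 2235 and a summit on arm X at position 19783732, 184 bp beyond the annotated 5′ end of the gene (19766465 to 19783548, minus strand); it stood at rank 2676 in replicate 2 and 2175 in replicate 3, and its summit lacked CAGGTAG. In an alternative chosen after seeing the data, random lists were drawn only from the 8780 genes with a relaxed summit within 1 kb. The early factors (ratio 1.92, permutation adjusted p = 0.145) and the housekeeping and heat-shock controls (ratio 1.95 in place of 2.10, permutation adjusted p = 0.0638) then no longer passed at 0.05, with ratios still above 1.

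Chemosensory and cuticle protein genes were bound less often than matched random lists. Of 230 chemosensory receptor and odorant-binding genes 5 (2.17%) were bound against 16.5% in random lists (permutation adjusted p = 0.000127), with Ir60e (signal 93.7), Obp99b (91.1), Or9a (83.0) and Gr32a (76.6) the strongest; replicate 2 alone gave 6 and replicate 3 alone 3. None of 114 cuticle protein genes was bound against 13.2% at random (permutation adjusted p = 0.000127). Against genes with a relaxed summit alone the chemosensory call was lost (ratio 0.505 in place of 0.131, permutation adjusted p = 0.257). Of 16 neuronal marker genes 2 were bound, elav (signal 273) and Syx1A (64.9), with 2 in replicate 2 alone and 1 in replicate 3 alone. Of 16 muscle genes 2 were bound, Msp300 (signal 306) and sls (123), with 3 in replicate 2 alone and 4 in replicate 3 alone, and of 14 fat body and hemocyte genes 0 were. Of 66 seminal fluid, yolk and eggshell genes 3 were bound. The strongest, Cp190, was taken in by its symbol and encodes an insulator protein. Of 20 neural stem cell genes brat, grh and dpn were bound, and of 20 regulators of other lineages fkh, trh and byn were. Of 15 Enhancer of split and Bearded family genes E(spl)m3-HLH and E(spl)m2-BFM were bound, with 2 in replicate 2 alone and 4 in replicate 3 alone. These 7 lists did not pass the permutation test (adjusted p from 0.102 to 0.879), but against unmatched random lists the seminal fluid, yolk and eggshell genes did (ratio 0.231 in place of 0.415, permutation adjusted p = 0.00285).

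**Figure D3:**
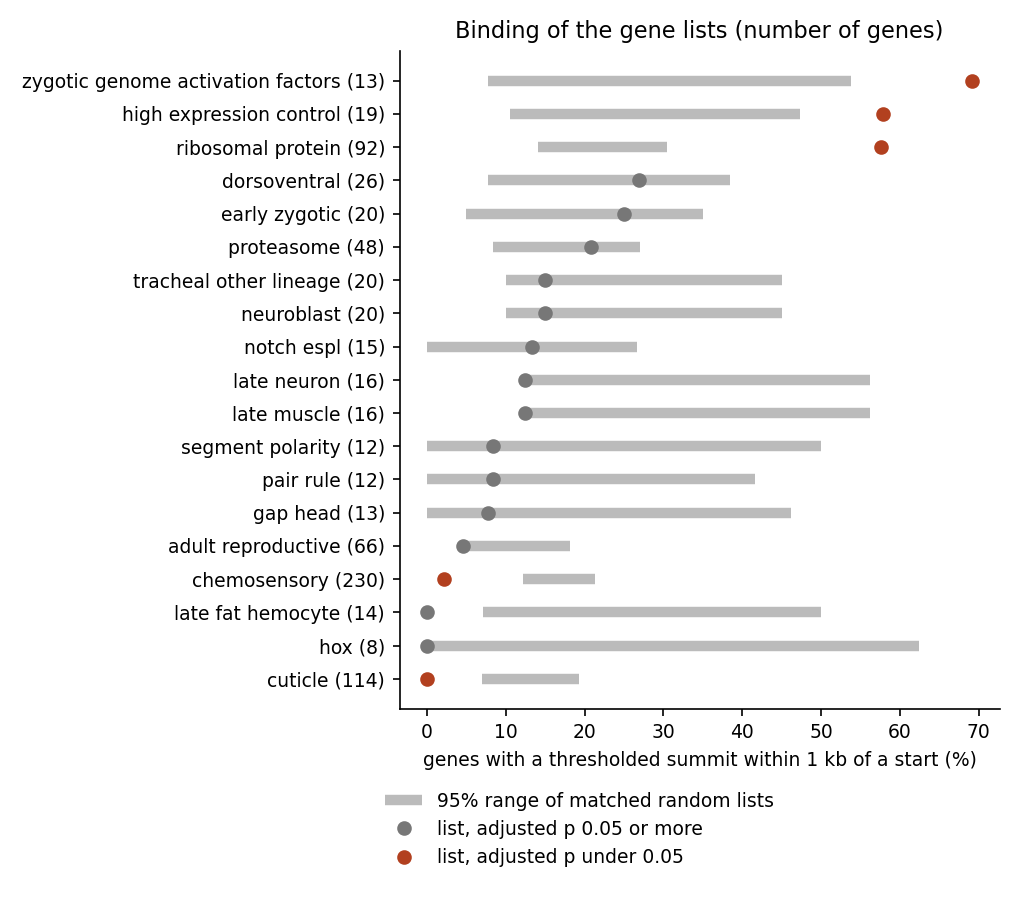
Share of genes (%) in each of 19 lists with a thresholded summit within 1 kb of a start (points, red where the adjusted permutation p is under 0.05) and the 95% range of 100000 matched random lists (grey bars); the number of genes is in parentheses. Ribosomal protein genes (57.6%), housekeeping and heat-shock controls (57.9%) and early chromatin factors (69.2%) lie above their ranges, and chemosensory (2.17%) and cuticle genes lie below theirs.

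The replicates shared most of their strongest peaks. Of the 2876 strongest peaks of replicate 2, 67.4% (interval 65.7 to 69.1%) had a summit within 200 bp of one of the 2876 strongest of replicate 3, and 67.2% of those of replicate 3 did so in reverse. Circularly shifted lists shared 0.840% on average and 1.43% at most (permutation p = 0.002, two-sided, the smallest that 1000 shifts can give). The shifts did not keep the preference for starts. The test therefore cannot separate agreement on single sites from a preference for starts common to both lists. Among the strongest 1000 the share was 72.8%. Of the thresholded peaks, 86.3% were among the 2876 strongest of replicate 2, 78.8% among those of replicate 3 and 66.9% among both. Across the 2851 thresholded peaks with a relaxed summit in each replicate, the signals had a Spearman rho of 0.528 (bootstrap interval 0.497 to 0.556) and a Pearson r of 0.645 on the log2 scale. Peaks are not independent replicates, and the thresholded peaks were chosen on the pooled signal, which narrows the range over which rho is taken. Over the 13455 relaxed pooled peaks with a summit in each replicate rho was 0.585, and over the 10604 of them below the threshold it was 0.285.

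**Figure D4:**
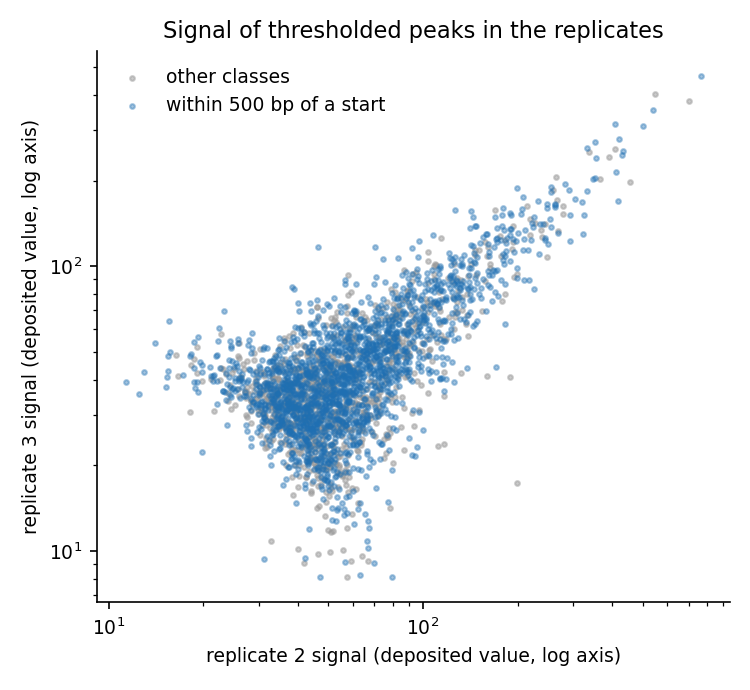
Deposited signal of 2851 thresholded peaks in replicate 2 (horizontal, log axis) and replicate 3 (vertical, log axis), with peaks within 500 bp of a start in blue and the others in grey. The strongest peaks lie along a common line and the weaker ones scatter (Spearman rho = 0.528).

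A minority of thresholded peaks stood far apart in the replicates when matched to the nearest summit. Each peak took the rank of the nearest relaxed summit within 200 bp, which need not be the strongest there. A weaker neighbouring summit could therefore give a low rank. By this measure the ranks differed by a median of 689 places, and by more than 5000 places at 162 peaks. The peaks that ranked far higher in replicate 3 lay nearest orion (rank 25306 in replicate 2 and 1493 in replicate 3), cindr (21261 and 1875), Pgm1 (19880 and 1247), gcl (16923 and 727) and Pyroxd1 (13804 and 474). Those that ranked far higher in replicate 2 lay nearest CG12974 (rank 632 in replicate 2 and 29414 in replicate 3), CG43402 (1240 and 29444), CG31021 (1016 and 28795), Ccs (1795 and 29553) and Mtl (842 and 25083). Of these 10 peaks 9 were at promoters, and CG43402 was the nearest gene to an intergenic summit 19507 bp away.

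Summits lay closer together along the arms than random placements did. Neighbouring summits lay a median of 15240.5 bp apart against 31919 bp for random placements (permutation p = 0.002, the smallest that 1000 placements can give). There were 687 genes with 3 or more summits in the gene extended by 5 kb, against 204 at random. Random placements did not keep the preference for starts, so neither value shows clustering beyond that preference. Of the gaps between neighbouring summits 7.91% were of 1000 bp or less. tara and the pannier cofactor gene ush had 10 each, and CHES-1-like, the kinase gene Raf and the myoblast fusion gene kirre had 9 each. These counts were not scaled to gene length, which ran from 27048 bp for CHES-1-like to 394149 bp for kirre. The count for ush takes in the strong peak nearest cbt, which lies inside ush. Arm 2L held 574 summits, 1.17 times its share of the assembly (exact binomial adjusted p = 0.000154). With replicate 3 alone arm 2R passed as well (585 summits, 1.11 times its share, exact binomial adjusted p = 0.0132). The binomial tests treat summits as independent, so their p-values can be too small where summits lie close together. Chromosome 4 held 7, 0.248 times its share (exact binomial adjusted p = 1.45e-05), although it held 467 of the relaxed pooled peaks, 1.59 times its share. With replicate 3 alone it held 12, 0.426 times its share, and with replicate 2 alone 7. No list had a summit on Y, so its share says nothing of binding there; with Y left out, a choice made after seeing the data, 2L stood at 1.14 and chromosome 4 at 0.242. In the dm6 lists no peak lay outside the major arms, and the authors' threshold kept 2746 peaks on the older dm3 build.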

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

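The tests of signal against CAGGTAG at distal peaks (after the negative relation over all peaks was seen) and of weak peaks near patterning genes were chosen only after the result was seen. The tests of each related word at promoter peaks were added during the analysis. The others were fixed beforehand. CAGGTAG was found below the authors' threshold, in peaks outside the main list: 537 of 27124 relaxed pooled peaks (1.98%) held it within 100 bp of the summit, against 1.27% of their flanks. On the dm3 build 36 relaxed pooled peaks lay outside the major arms, 31 of them on heterochromatic sequence, with a best rank of 5422, and no thresholded peak did.

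Promoter peaks made up most of the thresholded list and held CAGGTAG in 1.35% of cases, against 1.59% of their flanks (ratio 0.847, exact McNemar p = 0.298). Replacement by related sites taken as a set is argued against: CAGGTAA, TAGGTAG, CAGGCAG or CAGGTAT were 0.908 times as frequent at the 1831 promoter peaks without CAGGTAG as in their flanks (bootstrap interval 0.731 to 1.105). The 4 words differed over all 1856 promoter peaks. TAGGTAG stood at 1.76 times its flanks (exact McNemar adjusted p = 0.0593) and CAGGTAA at 1.03. CAGGCAG stood at 0.764 and CAGGTAT at 0.708. Replacement by TAGGTAG therefore stays open. Precipitation of open chromatin at highly transcribed genes stays open, since ribosomal protein, proteasome and control genes together were bound in 74 of 159 cases, 2.21 times the random mean (95% range of random lists 0.717 to 1.28). Transcription was not measured, and the control genes include heat-shock genes. A tagged factor other than the one on the label stays open: at distal thresholded peaks rho of signal and CAGGTAG was −0.0914 (interval −0.143 to −0.0317), but these peaks held the word 2.75 times as often as their flanks, and weak peaks near patterning genes held it 3.36 times as often as others, though only 2.19 times as often as their own flanks (interval 1.24 to 4.00), so that part of the 3.36 may lie in the sequence of the loci. No biological explanation was tested, and the 0 to 24 hour range of ages, most of it after the first wave of zygotic transcription, remains open too.

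By the nearest relaxed summit, the replicates ranked a minority of thresholded peaks very differently. The pooled signal followed replicate 2 (rho 0.882) more closely than replicate 3 (rho 0.786), a difference of 0.0960 beyond its bootstrap spread (interval 0.0779 to 0.115). The interval straddled the bound of 0.1 set beforehand, so whether 1 library dominated the pooled reads to that degree was left undecided. Repeats were left undecided as well: 8 of the 286 most discordant summits (2.80%) lay in masked sequence against 1.60% of the rest, a ratio of 1.75 (interval 0.630 to 3.28). Matching to a weaker neighbouring summit was not tested as a source of the differences and stays open. No biological explanation was tested, since the replicates form 1 group.

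The excess of CAGGTAG below the threshold did not come from shoulders of stronger peaks. Without relaxed peaks within 1 kb of a thresholded summit it was 1.58 times the flanks (bootstrap interval 1.42 to 1.78). Over all 27124 peaks it was 1.56 times (interval 1.40 to 1.74), so the threshold may leave out sites that the word marks. The design gives no group that would test a biological explanation of the whole excess. Early binding diluted among older embryos was examined only near patterning genes (the ratio of 3.36 above) and stays open.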

How the results depend on the processing

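The share of peaks with CAGGTAG was the result most dependent on the processing. With promoter peaks alone it was 1.35% and in the strongest 1438 peaks 0.695%, below the flanks in both, neither past the test. It passed with promoter peaks left out (3.24%), and at an unchanged 2.02% against flanks 500 bp away (ratio 1.45) and random placements (ratio 1.85). Taking 1 replicate alone gave 1.77 to 2.75%, past the test in replicate 3 alone. The values with and without promoter peaks follow from where the word lies; for the rest the cause was not tested. Windows of 50 and 250 bp, the shorter word, the 5 related sites, flanks 2000 bp away and relaxed peaks as background kept it above the background and not past the test. The thresholded count was by construction 1438 in the stricter list and 30000 in the relaxed pooled list. The Spearman correlation of signal between replicates was 0.607 with summits matched within 50 bp and 0.589 in the strongest 1438 peaks. A window of 50 bp gave 699 enriched 7-mer pairs in place of 1093, with less sequence searched. With random lists drawn from genes with a relaxed summit, chosen after seeing the data, 1 list was bound more often in place of 3, from fewer genes. The dm3 build added 36 relaxed peaks outside the major arms where dm6 had 0. Of 59 alternatives for the main results 46 kept the direction and side of the threshold or, without a test, the size: within 1.5 times for counts and inside the bootstrap interval for the correlation of signal. Of 245 for single arms, words and lists (median ranks within 1.5 times) 211 did. Another 15 changed direction, and in each of these neither the ratio in the full list nor that of the alternative passed. In the strongest 1438 peaks the ratio became 1.004 for arm X, 0.571 for CAGGTAG, 0.857 for CAGGTAA and 0.964 for GAGAG. With 1 replicate alone it ran from 0.957 to 1.02 for arm X, 0.867 to 1.08 for TAATCC, 0.965 to 1.45 for dorsoventral genes and 0.870 to 1.53 for proteasome genes. It was 0.741 for dorsoventral genes within 500 bp of a start, 1.40 for segment polarity genes by nearest start and 0.676 for Enhancer of split and Bearded genes against unmatched lists. Against genes with a relaxed summit it was 0.976 for dorsoventral, 0.997 for proteasome, 1.16 for seminal fluid, yolk and eggshell, and 0.621 for Enhancer of split and Bearded genes. The remaining 19 were 8 calls lost, 3 gained and 8 values changed in size. Replicate overlap ran from 45.4% (summits within 50 bp) to 72.8% (strongest 1000). No paired analysis was possible because there is 1 group. Depth is unknown, so what it limits could not be measured.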

Other observations

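All tests in this part were chosen after the results of the report were seen. Weak peaks at patterning genes held CAGGTAG often. Of 357 relaxed pooled peaks below the threshold and within 5 kb of a start of 81 early zygotic, gap, pair-rule, segment polarity and dorsoventral genes, 23 (6.44%) held the word at the summit. Near starts of other genes 388 of 20246 (1.92%) did, a ratio of 3.36 (bootstrap interval 2.06 to 4.82, Fisher's exact test p = 9.27e-07). The 23 peaks include those of sisA, sc, hb and odd, whose summits were already known from the report's results to hold the word. No value without them was computed, so the p-value partly restates what had been seen. The 23 peaks lay at 22 genes, named here after their values were seen. They included slp1 (119 bp upstream of the start, rank 3553), tld (276 bp upstream, rank 3746), tll (336 bp upstream, rank 6201), sc (48 bp upstream, rank 6728), halo (50 bp upstream, rank 10351), odd (49 bp upstream, rank 12456) and gt (195 bp upstream, rank 17041), each with a relaxed summit within 200 bp in both replicates. Peaks at sisA (rank 15800), hb (rank 19288) and twi (rank 28522) had one in replicate 2 alone, and those at zen (rank 15664) and bnk (rank 17139) in replicate 3 alone. Of the 23 peaks 15 had one in replicate 2 and 17 in replicate 3, and most had one in 1 replicate alone. Among all 27124 relaxed pooled peaks below the threshold, 10604 had one in both replicates. A hypothesis is that early binding at these genes may be diluted among embryos of up to 24 hours. Sequence of the loci rather than of the summits stays open: the same peaks held the word 2.19 times as often as their own flanks (interval 1.24 to 4.00), across the bound of 1.5.

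Promoters of mitochondrial ribosomal protein genes were bound more often than matched random lists. Of 73 such genes 28 (38.4%) were bound against 11.8% in matched random lists, a ratio of 3.26 (permutation adjusted p = 6e-05 over 3 lists, from the smallest p that the draws can give), led by mRpL41 (signal 627), mRpS23 (592), mRpL23 (514) and mRpS10 (490). This list was taken by symbol prefix, and mRpL41 and mRpS23 (whose peak is the one nearest CenG1A) had been seen among the 20 strongest peaks before it was written. Without them 26 of 71 were bound, a ratio of 3.08 (permutation adjusted p = 4e-05 over 2 lists). Genes with a divergent start within 1 kb were bound more often than other genes (ratio 2.93), and the random lists were not matched on this. How much of the ratio for mitochondrial ribosomal protein genes comes from shared promoters was not tested. The ratio of 2.20 for 21 genes of insulator and chromatin architecture proteins says nothing, because 5 of them (Chro, Cp190, Trl, Dref and Clamp) had been seen, or sat in a list already counted, before the list was written. Without these 5, 7 of 16 were bound, a ratio of 2.06, which did not pass (permutation adjusted p = 0.0698). Of 34 DNA replication genes 7 were bound, a ratio of 1.03 (permutation adjusted p = 1).

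TATCGATA was less frequent at promoter peaks far below the threshold. It lay at 188 of 1856 thresholded promoter peaks (10.1%) and at 426 of 7402 promoter peaks below the threshold (5.76%), a ratio of 1.76 (bootstrap interval 1.48 to 2.06, Fisher's exact test p = 1.07e-10). The difference did not lie at the threshold: at ranks 2877 to 5752 136 of 1481 promoter peaks (9.18%) held it, a ratio of 1.103 (interval 0.910 to 1.36), and at ranks 1 to 1000 63 of 706 (8.92%) did. A preference of the thresholded peaks for the word was therefore left undecided. GGTCACAC had 5.28% against 5.46% of all promoter peaks below the threshold, a ratio of 0.967 (interval 0.770 to 1.18), and 0.626 times the share at ranks 2877 to 5752 (interval 0.493 to 0.810). Among thresholded promoter peaks its share was 2.83% at ranks 1 to 1000, 5.74% at ranks 1001 to 2000 and 8.03% at ranks 2001 to 2876.

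Peaks favoured promoters shared by genes on opposite strands. Of thresholded promoter summits 746 of 1856 (40.2%) lay within 500 bp of starts on both strands, against 1333 of 7402 (18.0%) below the threshold, a ratio of 2.23 (bootstrap interval 2.07 to 2.40, Fisher's exact test p = 1.21e-84). Of 4649 genes with a divergent start within 1 kb 35.1% were bound, against 11.98% of 9319 other genes, a ratio of 2.93 (interval 2.74 to 3.13). In such pairs 1 summit can count for both genes, so this ratio overstates the number of separate binding events.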
